A study of Mus musculus with 18 samples.

How the data were processed

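Total RNA from 18 samples of mouse embryonic stem (ES) cells of the AB1 line was measured, each sample on 1 single-colour Affymetrix GeneChip array. Per the labels' protocols, cDNA was made with a 3' amplification kit and the transcribed cRNA carried a biotin label. Cells were wild type or had both copies of Cyp26a1 disrupted, and are called knockout here. Cyp26a1 encodes a cytochrome P450 that breaks down retinoic acid (RA), the vitamin A derivative that acts through nuclear receptors. The groups of each genotype were untreated control cells at 8 h (3 arrays), 100 nM RA for 8 h (3 arrays) and 100 nM RA for 72 h (2 arrays), all with leukemia inhibitory factor (LIF), the cytokine that keeps mouse ES cells undifferentiated. A further array per genotype held control cells kept without LIF for 8 h. The labels list no 72 h control, so the effect of RA over 72 h and that of time are not separated here.

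The authors deposited a table of linear signal intensity, 1 value per probe set and array. Per the submitters' processing notes the intensity values came from MAS5, Affymetrix's statistical algorithm. Its version and background settings are not given in the sources used here. Tested on the table, every value was positive and every array had a mean of 500 after trimming 2% at each end, so the arrays had been brought to a common level before deposition. The table held 45101 probe sets. Gene symbols came from the platform annotation: 34958 probe sets had 1 symbol, 932 had several and named no gene here, and 9211 were not listed and stay unnamed. Of the single-symbol probe sets, 34754 matched a RefSeq gene record of assembly GRCm38.p6 by Entrez number. That update changed 0 symbols. The RefSeq table was used for chromosome names and for the order of neighbouring genes only, since the files name no genome build. No column outside the series was present in the table.

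Each array was rescaled to a trimmed mean of 500, values under 50 were set to 50, and log2 was taken. Between 41.6% and 48.3% of the probe sets of an array lay at that floor. A fold change against a group whose arrays all lay at the floor is a lower bound and is written with "at least". A difference of 2 responses that involves such groups is not a bound, and is given as computed from floored values. Where a gene had several probe sets, the 1 with the highest mean log2 over the 18 arrays stood for it. This gave 18194 genes. A gene was tested when at least 2 arrays of the fit reached 100, which left 11388 genes. No gene named in the text had another probe set that went the opposite way with an unadjusted p under 0.05. Arrays carry no count depth: the number of arrays and the signal over background limit the precision. The median standard error of a log2 difference was 0.19 for 3 arrays against 3 and 0.24 for 2 against 2.

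Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). The 16 arrays of the 6 replicated groups shared a fit with 10 residual degrees of freedom. Benjamini-Hochberg adjustment ran over all genes tested in each comparison, with a threshold of 0.05, and "rose", "fell" and "called" are used of genes past it. Every adjusted p in the text is from limma and two-sided. Log2 differences are given with their standard error as "±". All contrasts but the last were drawn from this fit, and LIF withdrawal was tested in a separate fit of 8 arrays with genotype as a term, with 10476 genes and 5 residual degrees of freedom. The labels say that treatments were repeated but not whether the repeats were separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

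The design, the alternatives, 17 gene lists and the rule for naming genes were fixed before the data were examined. The rule names Cyp26a1 in each comparison and the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap on any array. In interactions it asks for the call alone. Of each list it names up to 4 members with the smallest adjusted p, or, where none was called, the 2 with the largest change. The text describes a part of the genes that the rule selects, and the others are not reported here. Genes named outside the rule are marked as chosen after their values were seen. The lists cover RA-induced genes, retinoid metabolism and transport, retinoid receptors and cofactors, Hox genes, pluripotency, the LIF-STAT3 response, extraembryonic endoderm, neural genes, primitive streak and mesoderm, trophectoderm, cell cycle inhibitors, proliferation, the Wnt response, germ cell and meiosis genes, the 2-cell-like state, fibroblast feeder markers, and immediate early and stress genes. No gene of the 2-cell-like list was measured here. Lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry stand beside it. Camera asks whether a list moved more than the other genes, and fry whether its genes moved on balance in 1 direction.

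The labels number some replicates. Titles with a number 2 or 3 were taken as such, and unnumbered titles were placed by their style, which is an inference. Whether the numbers pair samples was checked on the deviations from the group means. All 18 same-number pairs between the 8 h groups correlated between 0.136 and 0.504, against a median of -0.15 for pairs with different numbers, and the 72 h pair correlated at 0.15. The numbers were therefore taken to pair the samples, and a fit with the number as a block (8 residual degrees of freedom) stands beside each result that it moved by more than 1.5 times. The Actb 3' to 5' signal ratio, a measure of RNA and labelling quality, also followed the number: 1.71 to 2.05 on the 8 arrays numbered 1, 1.49 to 1.72 on the 6 numbered 2, and 1.24 to 1.41 on the 4 numbered 3. Each number held arrays of both genotypes, and the block covers this difference.

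Correlations between arrays over all probe sets on the log2 scale ranged from 0.956 to 0.991, with 0.978 as the lowest within a group, and no 2 arrays held the same values. The scripts were tested on simulated data with 100 changed genes per fold size among 11388. For RA at 8 h in wild type, 71% of 2-fold and 99% of 4-fold changes were recovered. For the genotypes at 72 h the shares were 61% and 91%, for the 8 h interaction 43% and 84%, for the 72 h interaction 27% and 76%, and for LIF withdrawal 59% and 95%. For LIF withdrawal a call in either direction counted. The simulated arrays had independent normal noise, no floor, no deviations shared within a replicate number and correct labels. The shares on the real arrays may therefore differ. Alternatives were quantile normalization, a floor of 100, log2 of the signal plus 32 without a floor, no filter, a filter at 200, every probe set tested, no intensity trend, a fit of only the groups compared, the replicate block, an added 2-fold minimum, and leaving out each array in turn. Where the last step left 1 array in a group, that array was assumed to vary like the others. Removing the genes of chromosomes 8 and 19, list tests with the block, a block in the fit of LIF withdrawal (3 residual degrees of freedom), and an exchange of the labels with and without LIF between the replicate 1 control arrays of each genotype were added after seeing the data. The labels stand as given in every other result.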

Results

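Transcript levels were measured on 18 arrays of mouse AB1 embryonic stem (ES) cells, wild type or with both copies of Cyp26a1 disrupted. Each genotype had 3 arrays of untreated control cells, 3 of cells given 100 nM retinoic acid (RA) for 8 h, 2 of cells given RA for 72 h, and 1 of control cells kept without LIF. The median signal of an array lay between 54.4 and 75.6 units, and between 39.9% and 45.3% of its probe sets reached 100 units. Changes below are log2 differences ± standard error with the limma adjusted p, over 11388 genes unless stated, and folds against a group at the floor of 50 units are lower bounds. In replicate 1 the LIF-induced gene Socs3 read 367 units in wild type and 215 in the knockout on the control array labelled with LIF, and 3800 and 4551 units on the array labelled without it. On the other 14 arrays, all labelled with LIF, it read 2628 to 6001 units. Calls that changed when these 2 labels were exchanged within each genotype are given below as "with the LIF labels exchanged".

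Cyp26a1, whose product is the cytochrome P450 that oxidises RA, had a signal of 57.9 ± 35.5 units (SD, n = 3) in wild-type control cells. It stood at 1008 ± 596 units (n = 3) after 8 h of RA and at 3307 ± 136 units (n = 2) after 72 h. In knockout cells the signal was 28.6 ± 21.9 units in controls, 201 ± 13.5 units after 8 h and 2974 ± 143 units after 72 h, with the same numbers of arrays. The arrays without LIF read 33.7 units in wild type and 53.8 units in the knockout. Between genotypes, Cyp26a1 was lower in knockout cells after 8 h of RA (-2.18 ± 0.29, adjusted p = 0.000762). The difference was -0.40 ± 0.29 in controls (adjusted p = 0.583) and -0.15 ± 0.35 after 72 h (adjusted p = 0.911), neither of them past the threshold. Where the probe set lies relative to the disrupted part of the gene is not known here, so its signal does not check the knockout. Cyp26a1 also lies on chromosome 19, whose genes as a group read higher in knockout cells.

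**Figure D1:**
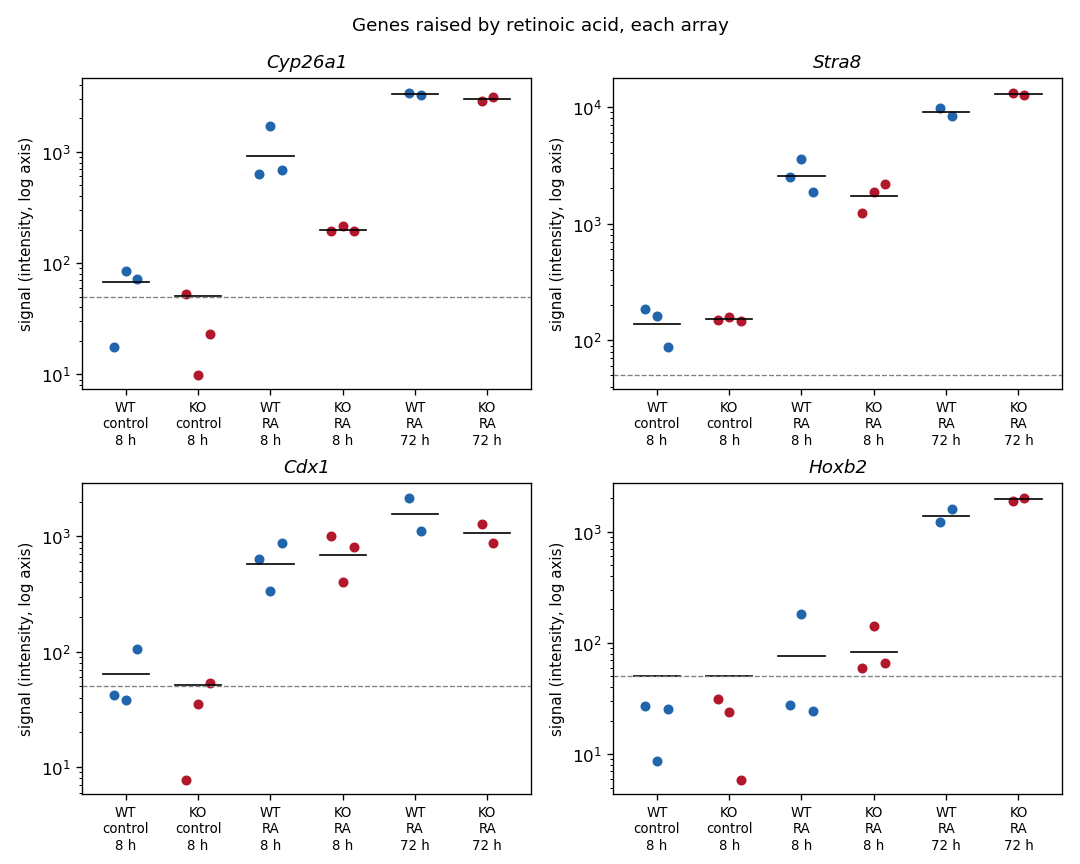
Signal of Cyp26a1, Stra8, Cdx1 and Hoxb2 (units, log axis) on each array of the 6 replicated groups, wild type in blue and knockout in red. Points are arrays, black lines the mean of the floored log2 values and the dashed line the floor of 50, and Cyp26a1 averaged 1008 units in wild type and 201 in the knockout after 8 h of RA.

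The response of wild-type ES cells to 8 h of RA was led by known targets of the RA receptors. Stra8, a gene of premeiotic germ cells that RA induces, rose 18.6-fold (4.22 ± 0.27, adjusted p = 6.80e-07, 3 arrays per group). Cyp26a1 itself rose 13.5-fold (3.76 ± 0.29, adjusted p = 4.69e-06). Cdx1, a caudal homeobox gene of the posterior embryo, rose by 3.17 ± 0.40, and Aqp3, a water and glycerol channel, by 2.74 ± 0.61. Cidea, a lipid droplet protein, rose by at least 2.32 ± 0.18 and Adgra2, an adhesion receptor that aids Wnt7 signalling, by at least 1.91 ± 0.17. The class I antigen gene H2-Bl (2.17 ± 0.32), the acid phosphatase Acp5 (2.03 ± 0.23) and the Groucho-related corepressor Tle6 (1.92 ± 0.22) rose as well. Among the genes that fell were Slc27a2, a fatty acid transporter (-1.95 ± 0.42, adjusted p = 0.0404), and Fst, the activin-binding protein follistatin (-1.58 ± 0.29). Ndrg1, a stress-responsive gene (-1.11 ± 0.22), Ddx58, the viral RNA sensor also called RIG-I (-1.04 ± 0.22), and the cationic amino acid transporter Slc7a3 (-0.93 ± 0.13) fell too.

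In all, 103 genes were called after 8 h of RA in wild type, 90 of them higher and 13 lower. With the replicate number as a block the count was 275, with 211 higher and 64 lower. It was 67 without the filter on dim genes, 60 with a 2-fold minimum, 67 without replicate 1 of the RA group, 58 without its replicate 3 and 160 with the LIF labels exchanged. A fit of these 6 arrays alone called 5 genes, Adgra2, Cidea and Stra8 with Ankrd44, an ankyrin subunit of a protein phosphatase, and Ptpmt1, a mitochondrial phosphatase, the last 2 chosen after their values were seen. Of the 13 RA-induced genes measured, 6 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 2.27e-16). These included Nrip1, a nuclear receptor corepressor that RA induces (1.88 ± 0.17). Of 13 genes of retinoid metabolism and transport, Cyp26a1 and the retinal reductase Dhrs3 (1.79 ± 0.24) rose and 0 fell, which held when adjusted over the list alone (camera adjusted p = 0.0207). That call gave adjusted p = 0.143 with an estimated correlation, 0.0656 with the block and 0.256 without the genes of chromosomes 8 and 19, which leaves out Cyp26a1. Among 10 retinoid receptors and cofactors, Nrip1 and the RA receptor Rarb (at least 0.97 ± 0.19) rose, 0 fell, and the 2 calls held when adjusted over the list alone (camera adjusted p = 0.0566, and 0.0152 over 9 genes tested with the LIF labels exchanged). None of 14 neural genes rose or fell, nor any when adjusted over the list alone, and their median was -0.28 (camera adjusted p = 0.0207). The neural result had adjusted p = 0.143 with an estimated correlation, 0.0725 without the genes of chromosomes 8 and 19 and 0.0923 with the LIF labels exchanged. Single members of other lists rose: Hoxb4, a homeobox gene of the hindbrain and trunk (1.43 ± 0.23), Pim1, a kinase gene downstream of STAT3 (1.17 ± 0.19), Dppa2, a chromatin regulator of pluripotent cells (0.73 ± 0.15), and Gadd45b, a growth arrest gene (0.75 ± 0.17). Of 12 immediate early and stress genes 0 rose and 0 fell (none when adjusted over the list alone), with camera adjusted p = 0.0566, and 0.0444 with the block.

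Knockout cells responded to 8 h of RA with many of the same genes. Cdx1 rose by 3.75 ± 0.40 (adjusted p = 0.000240, 3 arrays per group) and Stra8 by 3.51 ± 0.27 (adjusted p = 4.10e-06). Cyp26a1 rose by 1.98 ± 0.29 (adjusted p = 0.00311) against control arrays of 52.6, 9.81 and 23.3 units, of which the last 2 were set to the floor, so that its fold is understated. With a floor of 100 the rise of Cyp26a1 was smaller and no longer called. H2-Bl rose by 3.11 ± 0.32, Adgra2 by at least 2.59 ± 0.17 and Cidea by at least 2.56 ± 0.18. Ltbp3, which tethers latent TGF-beta in the matrix, rose by 2.44 ± 0.28, and Prrx2, a homeobox gene of mesenchyme, by 2.41 ± 0.42. The smallest adjusted p was that of Ankrd44 (2.03 ± 0.12, adjusted p = 3.04e-07). The ecto-5'-nucleotidase gene Nt5e rose by 1.99 ± 0.31. The falls were smaller: Mcc, named for its mutation in colorectal cancer (-1.50 ± 0.34), Kndc1, a guanine nucleotide exchange factor of neurons (-1.35 ± 0.30, not called with the LIF labels exchanged), Ndrg1 (-1.09 ± 0.22), the ETS repressor Etv6 (-0.94 ± 0.17), Slc7a3 (-0.72 ± 0.13) and the R-spondin receptor Lgr4 (-0.69 ± 0.15).

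The knockout's count after 8 h of RA was 109 genes, 98 higher and 11 lower, and 342 with the block, 245 higher and 97 lower. It fell to 57 without the filter and to 24 in a fit of these 6 arrays alone. Leaving out a control array gave 64 (replicate 1) or 41 (replicate 2), and leaving out an RA array gave 40 (replicate 1), 72 (replicate 2) or 36 (replicate 3). Of the 13 RA-induced genes 6 rose and 0 fell, and 7 rose when adjusted over the list alone (camera adjusted p = 5.84e-13). Nrip1 (1.15 ± 0.17) was again among them. In retinoid metabolism and transport, Cyp26a1 and Dhrs3 (1.21 ± 0.24) rose out of 13, 0 fell, and 3 rose when adjusted over the list alone (camera adjusted p = 0.0279). That list had adjusted p = 0.129 with an estimated correlation, 0.0800 with the block, 0.219 without the genes of chromosomes 8 and 19 and 0.0580 with the LIF labels exchanged. Nrip1 and Rarb (at least 1.01 ± 0.19) rose among 10 receptors and cofactors, 0 fell, and adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.0185, and adjusted p = 0.129 with an estimated correlation). Of 19 Hox genes only Hoxb4 rose (1.50 ± 0.23), also when adjusted over the list alone, and 0 fell (camera adjusted p = 0.00266, and adjusted p = 0.129 with an estimated correlation). The neural list of 14 had 0 rises and 0 falls, or 3 falls when adjusted over the list alone, and a median of -0.13 (camera adjusted p = 0.0480). Its adjusted p = 0.191 with an estimated correlation, and 0.0999 with the block. Of 10 germ cell and meiosis genes Stra8 rose, 0 fell and 2 rose when adjusted over the list alone (camera adjusted p = 0.0480). That result had adjusted p = 0.253 with an estimated correlation, 0.0999 with the block, 0.0727 with quantile normalization and 0.103 with the LIF labels exchanged. Gata6, the endoderm transcription factor, rose by 1.74 ± 0.33 (adjusted p = 0.0190, or 0.0683 with the LIF labels exchanged) in knockout cells and had a difference of 1.07 ± 0.33 in wild type (adjusted p = 0.229, or 0.0468 with the block).

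Whether the genotypes responded differently to 8 h of RA was tested as an interaction, and 0 of 11388 genes were called by limma, also with the block. At an unadjusted p under 0.05 there were 211 genes, or 367 with the block, and the smallest adjusted p was 1, or 0.728 with the block. Both counts are under the share of 0.05 of the genes tested that would pass with no effect at all. The p-values of this test thus ran large, and 0 calls do not show that the responses were equal. For Cyp26a1 the difference of responses was -1.78 ± 0.41 (adjusted p = 1), a value that depends on the floor: it was -2.18 with a floor of 100 and -1.48 with log2 of the signal plus 32. The interaction was -0.71 ± 0.38 for Stra8, -0.73 ± 0.24 for Nrip1 and 0.67 ± 0.47 for Gata6, all with adjusted p = 1. No list was called in the interaction: the 13 RA-induced genes had 0 rises and 0 falls, 2 falls when adjusted over the list alone, and camera adjusted p = 0.166. The Hox list had 0 of 19 called, 0 when adjusted over the list alone, and camera adjusted p = 0.173. Without the filter on dim genes 2 genes passed, AU041133, a zinc finger gene (-0.57, adjusted p = 0.0439), and Fut4, a fucosyltransferase (-0.83, adjusted p = 0.00678), both chosen after their values were seen.

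The genes higher after 8 h of RA overlapped between genotypes: 63 were called higher in both, where 0.774 would be shared by chance, and 4 were called lower in both against 0.0126. Of the 103 genes called in wild type, 99 had the same sign in the knockout. Across genes the changes correlated with a Pearson coefficient of 0.597 and a Spearman coefficient of 0.427, and genes are not independent replicates. The Pearson coefficient was 0.697 with the filter at 200 units and 0.505 to 0.602 with each array left out. No array was shared by the 2 comparisons.

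Genes of chromosome 19 read higher in knockout cells and genes in parts of chromosome 8 read lower, in each condition. Over the 414 genes of chromosome 19 the median difference was 0.47 in controls, 0.48 after 8 h of RA and 0.48 after 72 h, and 90.6% of them lay above 0 in the mean of the conditions. Every one of 13 windows of neighbouring genes along chromosome 19 had a median above 0, from 0.40 to 0.54. Within pairs of arrays with the same replicate number, the chromosome's median ran from 0.43 to 0.53. The 638 genes of chromosome 8 had medians of -0.25, -0.24 and -0.29 in the same conditions. On chromosome 8 the shift fell into stretches: 270 genes from Frg1 to Ccdc113 had a median of -0.43 and the 128 genes from Vac14 to the end one of -0.39. The 150 genes at the start had a median of 0.00242 and the 90 between the lower stretches one of -0.00095. The boundary genes were chosen after their values were seen. With quantile normalization the medians of the mean difference were 0.50 on chromosome 19 and -0.24 on chromosome 8. RA at 8 h left chromosome 19 at a median of 0.01 in wild type and 0.03 in the knockout.

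**Figure D2:**
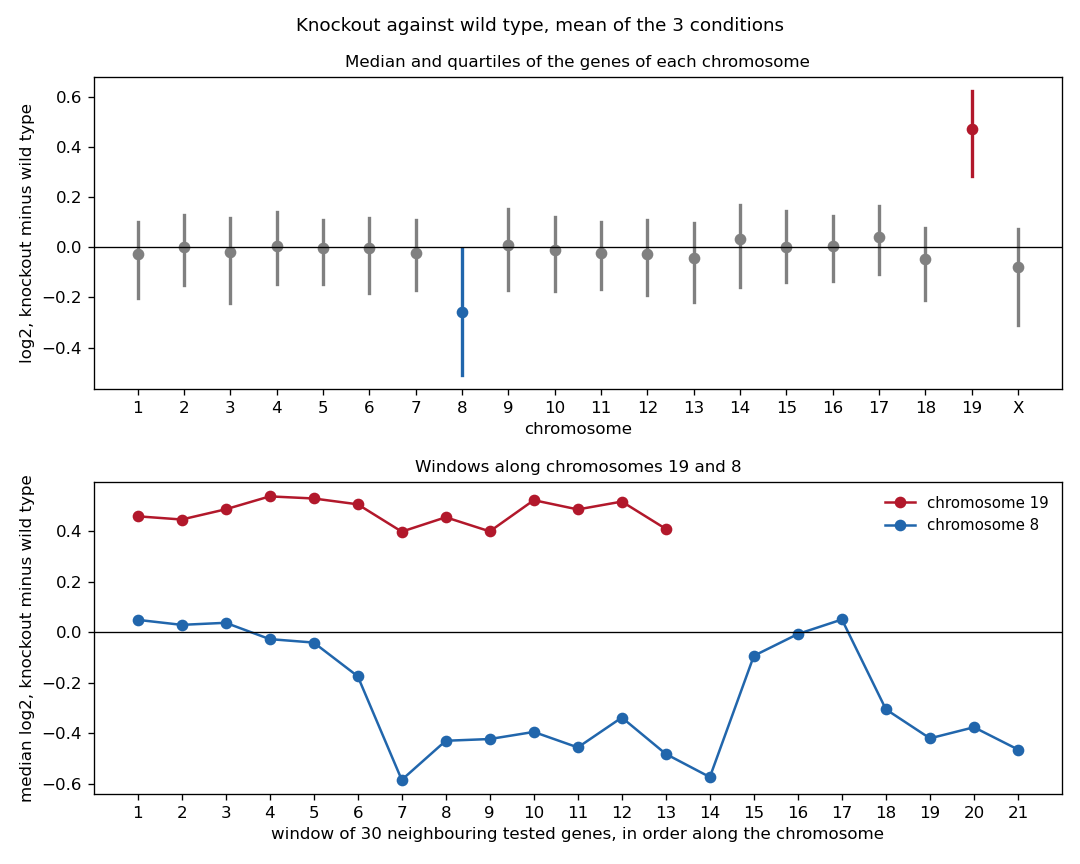
Knockout against wild type, mean over conditions: the median and quartiles of the log2 difference per chromosome, and the median in windows of 30 neighbouring genes (last window 54 on chromosome 19 and 38 on chromosome 8) along both chromosomes. Chromosome 19 had a median of 0.47 and chromosome 8 of -0.26, and windows of chromosome 8 ran from -0.58 to 0.05.

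In control cells several X-linked transcripts read lower in the knockout. Wnk3, a kinase that regulates chloride transport, was lower by at least 4.08 ± 0.38 (adjusted p = 6.10e-05, 3 arrays per group), with every knockout array at the floor. Fmr1nb, a cancer and testis antigen beside the fragile X gene, fell (-3.46 ± 0.79), as did Klhl13, a ubiquitin ligase adaptor (-2.84 ± 0.62), and Mageb16, a melanoma antigen family member (-2.48 ± 0.65). Sh3bgrl, a small thioredoxin-like protein gene, was lower by at least 2.31 ± 0.21 (adjusted p = 6.10e-05). Off the X chromosome, Lncenc1, a non-coding RNA of ES cells (-2.73 ± 0.40), the lysine-degrading enzyme gene Aass (-2.68 ± 0.66) and Palld, an actin cross-linker on chromosome 8 (-2.12 ± 0.36), fell. Endoderm genes fell as well: Gata6 (-2.13 ± 0.33, adjusted p = 0.00236), the endocytic receptor Cubn (-2.21 ± 0.52, or -1.79 and not called with the LIF labels exchanged) and its partner Amn (-1.47 ± 0.33), and the laminin chain Lamb1 (-1.28 ± 0.29). Bnip3, a mitophagy receptor that hypoxia induces, rose the most (1.67 ± 0.41, adjusted p = 0.0293), followed by Atrnl1, an attractin relative on chromosome 19 (1.42 ± 0.28), and Tlr2, a receptor for bacterial lipoproteins (1.41 ± 0.19, adjusted p = 0.00135). The mitochondrial subunit Ndufa4l2, another hypoxia-induced gene (1.23 ± 0.26, or 0.77 and not called with the LIF labels exchanged), and the neural arginine methyltransferase Prmt8 (1.21 ± 0.27) rose too.

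Between genotypes 528 genes were called in control cells, 208 higher and 320 lower, with 1069 under the block, 458 higher and 611 lower. Chromosome 19 held 126 of the 208 higher genes (Fisher's exact p = 1.23e-132) and chromosome 8 held 110 of the 320 lower genes (Fisher's exact p = 8.75e-59). Without the genes of both chromosomes 201 were called, 47 higher and 154 lower. A 2-fold minimum left 135, and a fit of these 6 arrays alone 14. The count was 297 without wild-type replicate 1, 253 without knockout replicate 2 and 307 without knockout replicate 3. Of 17 extraembryonic endoderm genes 0 rose and 5 fell, or 8 when adjusted over the list alone, with a median of -0.95 (camera adjusted p = 1.86e-05). This list had adjusted p = 0.413 with an estimated correlation. Of 13 cell cycle inhibitors 0 rose and 3 fell, 4 when adjusted over the list alone (camera adjusted p = 0.0145, adjusted p = 0.128 with an estimated correlation, and 0.0943 with the LIF labels exchanged). These were Ccng1, a p53 target (-0.97 ± 0.19), and the kinase inhibitors Cdkn2b (-1.23 ± 0.29, or -0.96 and not called with the LIF labels exchanged) and Cdkn1c (-1.85 ± 0.45). Among 28 pluripotency genes 2 rose and 2 fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.747), with a median of 0.11 and a mean of -0.013. The Nodal antagonists Lefty1 (-1.34 ± 0.19) and Lefty2 (-1.35 ± 0.30) fell, and the Nodal coreceptor Tdgf1 (0.50 ± 0.13) and the germ cell regulator Prdm14 (1.10 ± 0.30) rose. Fabp5, which carries RA and fatty acids in the cell, fell by 1.08 on the log2 scale (adjusted p = 0.00236), and the germ cell helicase Ddx4 fell by 1.17 (adjusted p = 0.00150).

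After 8 h of RA the knockout differed from wild type in many of the same genes, on other arrays. Wnk3 was lower by at least 3.77 ± 0.38 (adjusted p = 0.000141, 3 arrays per group), and Fmr1nb (-3.72 ± 0.79), Mageb16 (-3.01 ± 0.65), Lncenc1 (-2.88 ± 0.40), Klhl13 (-2.84 ± 0.62) and Palld (-2.78 ± 0.36) fell. The peptide transporter Slc15a2 (-2.32 ± 0.23, adjusted p = 0.000108) and Fbp2, an enzyme of gluconeogenesis (-2.30 ± 0.39), also fell. Aire, the thymic regulator of self-antigens that ES cells express as well, rose the most (2.04 ± 0.54, adjusted p = 0.0428). Bnip3 (1.61 ± 0.41), Tlr2 (1.61 ± 0.19) and the neural progenitor gene Sox3 (1.28 ± 0.30) rose, as did the desaturase Fads2 (1.25 ± 0.31) and the nuclear RNA Malat1 (1.20 ± 0.27), both on chromosome 19. Of the 13 RA-induced genes 0 rose, and Cyp26a1 (-2.18 ± 0.29) and Nrip1 (-0.66 ± 0.17) fell, also when adjusted over the list alone (camera adjusted p = 0.188).

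The count between genotypes after 8 h of RA was 525, 194 higher and 331 lower, and 1114 with the block, 450 higher and 664 lower. Chromosome 19 held 130 of the higher genes (Fisher's exact p = 6.38e-146) and chromosome 8 held 111 of the lower (Fisher's exact p = 4.74e-58). The count was 148 without the genes of those chromosomes, 21 higher and 127 lower, 126 with a 2-fold minimum and 34 in a fit of these arrays alone. Leaving out a wild-type array gave 287, 293 or 348 for replicates 1 to 3, and leaving out a knockout array gave 252 for replicate 1 and 243 for replicate 3. Genes called in controls were called again: 127 higher in both against 3.54 by chance and 213 lower in both against 9.30, with a Pearson coefficient of 0.708 across genes. Of 17 extraembryonic endoderm genes 0 rose and 4 fell, 5 when adjusted over the list alone (camera adjusted p = 0.000665, and adjusted p = 0.469 with an estimated correlation). They were Lamb1 (-1.67 ± 0.29), Gata6 (-1.46 ± 0.33), the growth factor receptor Pdgfra (lower by at least 1.39 ± 0.28) and Cubn (lower by at least 2.21 ± 0.52). With the LIF labels exchanged, which leaves the values of these arrays as they are but changes the shared spread and the genes tested, Gata6 (adjusted p = 0.0649) and Cubn (adjusted p = 0.0581) were not called. Of 13 cell cycle inhibitors 0 rose and 2 fell, Ccng1 (-0.87 ± 0.19) and Cdkn1c (-1.65 ± 0.45), with 4 falls when adjusted over the list alone. That list had camera adjusted p = 0.0645, with 0.0450 under the block, 0.0385 without the genes of chromosomes 8 and 19 and 0.0417 with the LIF labels exchanged. The LIF-STAT3 list, not called here with the labels as given (camera adjusted p = 0.188), had 0.0481 with them exchanged. Lefty1 (-1.59 ± 0.19), Lefty2 (-1.15 ± 0.30), Fabp5 (-1.16 ± 0.17) and Ddx4 (-1.32 ± 0.16) fell.

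Several contractile genes were among the largest falls in the knockout after 72 h of RA. Tagln, the actin-binding protein transgelin, fell by 5.46 on the log2 scale (SE 0.27, adjusted p = 2.35e-08, 2 arrays per group), from a signal of 4103 units in wild type to 97.5 units. Acta2, smooth muscle actin (-4.09 ± 0.51), and Myl9, a myosin light chain (-3.26 ± 0.35), fell, and Acta1, skeletal actin, was lower by at least 3.44 ± 0.34. In a list of 24 contractile and adhesion genes, drawn up after the values were seen, 0 rose, 17 fell and 7 were not called (camera p = 2.46e-05 with an estimated correlation). Without Tagln, Acta2, Acta1, Myl9 and Palld, which were named before the list was drawn up, 0 of the other 19 rose and 12 fell (camera p = 8.65e-05 with an estimated correlation). The annexin Anxa3 (-3.65 ± 0.26, adjusted p = 2.00e-06) and Sh3bgrl (-3.58 ± 0.26) fell. Vwa5a, a von Willebrand domain gene, was lower by at least 3.31 ± 0.44 and Wnk3 by at least 3.30 ± 0.47. Mageb16 (-4.16 ± 0.80) and Fmr1nb (-3.97 ± 0.97) fell again. Bnip3 (2.56 ± 0.50, adjusted p = 0.00819), Ndufa4l2 (2.36 ± 0.32), the linker histone H1f2 (2.28 ± 0.37) and Slc16a3, the lactate exporter that hypoxia induces (1.88 ± 0.40), rose. Prmt8 (1.88 ± 0.32), the dorsal neural tube gene Olig3 (1.64 ± 0.22) and Actn3, an actinin on chromosome 19 (2.15 ± 0.40), rose too.

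Called genes at 72 h numbered 463, 158 higher and 305 lower, and 1004 with the block, 405 higher and 599 lower. Chromosome 19 held 81 of the 158 and chromosome 8 held 55 of the 305. Without the genes of both chromosomes 274 were called, 61 higher and 213 lower, against 267 with a 2-fold minimum and 73 in a fit of these 4 arrays alone. Leaving out a wild-type array gave 245 (replicate 1) or 177 (replicate 2), and leaving out a knockout array gave 203 (replicate 1) or 190 (replicate 2). Of 8 trophectoderm genes, which mark the outer layer of the blastocyst, 0 rose and 4 fell, 6 when adjusted over the list alone (camera adjusted p = 4.09e-08). The keratins Krt18 (-2.60 ± 0.40), Krt7 (-1.68 ± 0.27) and Krt8 (-1.62 ± 0.33) fell, and the transcription factor Gata3 was lower by at least 1.45 ± 0.23. Of 13 cell cycle inhibitors 0 rose and 2 fell, Cdkn2b (-2.57 ± 0.36) and the p53 target Cdkn1a (-1.07 ± 0.22), with 5 falls when adjusted over the list alone (camera adjusted p = 0.000964). The RA-induced list had 0 rises and 1 fall of 13, Meis1, a homeobox cofactor of Hox proteins (-1.53 ± 0.30), or 3 falls when adjusted over the list alone (camera adjusted p = 0.00257, and adjusted p = 0.0580 with an estimated correlation). Of 28 pluripotency genes, Tdgf1 (1.11 ± 0.16) and the chromatin protein Utf1 (0.75 ± 0.20) rose, 0 fell, and 6 rose when adjusted over the list alone (camera adjusted p = 0.00150, and adjusted p = 0.0940 with an estimated correlation). None of 24 proliferation genes rose or fell, nor any when adjusted over the list alone, at a median of 0.16 (camera adjusted p = 0.0461). That list had adjusted p = 0.183 with an estimated correlation, and 0.329 with quantile normalization.

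The mean difference of the genotypes over the control, 8 h and 72 h conditions showed the same X-linked and hypoxia-induced genes with smaller errors. Fmr1nb (-3.72 ± 0.49), Mageb16 (-3.22 ± 0.41), Klhl13 (-2.97 ± 0.39), Sh3bgrl (-2.70 ± 0.13, adjusted p = 2.13e-08) and Rhox5, a placental and testis homeobox gene of the X chromosome (-2.67 ± 0.54), fell. Wnk3 was lower by at least 3.72 ± 0.24. Lncenc1 (-2.79 ± 0.25), Palld (-2.26 ± 0.22), Anxa3 (-2.18 ± 0.13) and Slc15a2 (-2.18 ± 0.14) fell. Bnip3 (1.95 ± 0.26, adjusted p = 9.86e-05), H1f2 (1.56 ± 0.19), Ndufa4l2 (1.51 ± 0.16) and Tlr2 (1.44 ± 0.12) rose, and so did Igf2bp3, an RNA-binding protein of embryonic and tumour cells (1.38 ± 0.28), and the glycolytic enzyme Tpi1 (1.11 ± 0.12). Cyp26a1 fell by 0.91 on the log2 scale (SE 0.18, adjusted p = 0.00245).

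Over the mean of conditions 2016 genes were called, 801 higher and 1215 lower, of which chromosome 19 held 252 of the higher and chromosome 8 held 259 of the lower. Without both chromosomes 1327 were called, 472 higher and 855 lower, and a 2-fold minimum left 143, 22 higher and 121 lower. Of 17 extraembryonic endoderm genes 0 rose and 8 fell, 10 when adjusted over the list alone (camera adjusted p = 0.000691, and adjusted p = 0.293 with an estimated correlation). Lamb1 (-1.24 ± 0.18), Cubn (-1.69 ± 0.32), Gata6 (-1.03 ± 0.21) and Pdgfra (-0.75 ± 0.17) were among them. Of 13 cell cycle inhibitors 0 rose and 7 fell, with 7 also when adjusted over the list alone, among them Cdkn2b (-1.46 ± 0.18), Ccng1 (-0.84 ± 0.12) and Cdkn1a (-0.69 ± 0.11) (camera adjusted p = 0.00205). Of 8 trophectoderm genes 0 rose and 4 fell, the same when adjusted over the list alone (camera adjusted p = 0.0193). Their median was 0.01 in controls (camera adjusted p = 0.787) and -0.01 after 8 h of RA (camera adjusted p = 0.731), against -1.36 after 72 h, so that the mean reflects the 72 h arrays. The mean's result had adjusted p = 0.142 with an estimated correlation, and 0.117 with quantile normalization. Of 28 pluripotency genes 6 rose and 2 fell, and 8 rose and 2 fell when adjusted over the list alone, led by Tdgf1 (0.67 ± 0.08) and the zinc finger gene Zfp42, also called Rex1 (0.26 ± 0.05), with Lefty1 (-0.90 ± 0.12) and Lefty2 (-0.83 ± 0.19) as the falls (camera adjusted p = 0.0422). That list had adjusted p = 0.293 with an estimated correlation, and 0.251 with quantile normalization. Of the 13 RA-induced genes 0 rose and 2 fell, Cyp26a1 and Meis1 (-0.76 ± 0.15), also when adjusted over the list alone (camera adjusted p = 0.0385, adjusted p = 0.211 with an estimated correlation, and 0.0518 without the genes of chromosomes 8 and 19). Of 24 proliferation genes 3 rose and 2 fell, with 5 and 2 when adjusted over the list alone (camera adjusted p = 0.0549, and 0.0334 with the block). The LIF-STAT3 list had camera adjusted p = 0.152, and 0.0294 with the LIF labels exchanged. The germ cell genes Ddx4 (-1.16 ± 0.10), Rec8, a meiotic cohesin (-0.63 ± 0.13), and Dazl, an RNA-binding protein (-1.51 ± 0.34), fell.

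Wild-type cells after 72 h of RA were set against the 8 h controls, so RA and time in culture are not separated in these changes. Tagln rose by at least 6.35 ± 0.24 (adjusted p = 6.65e-10, 2 arrays against 3), Stra8 by 6.03 ± 0.30 and Pmp22, a myelin and growth arrest protein gene, by 5.81 ± 0.24. Cyp26a1 rose by 5.62 ± 0.32 (adjusted p = 3.32e-08), to the signal of 3307 units given above. The hindbrain gene Hoxb2 rose by at least 4.79 ± 0.46, and Gas1, a growth arrest gene that also serves as a hedgehog coreceptor, by 4.76 ± 0.40. Cdx1 (4.61 ± 0.45) and Bhmt, an enzyme of methionine metabolism (4.59 ± 0.37), rose, and the corepressor Zfp703 rose by at least 4.61 ± 0.41. Enox1, a cell surface oxidase gene, fell (-3.64 ± 0.34), Nkx6-3, a homeobox gene of the gut, was lower by at least 3.64 ± 0.50 and Dab1, a reelin adaptor, by at least 3.17 ± 0.23. The nicotinic receptor subunit Chrna9 (-3.33 ± 0.20), the zinc finger gene Bnc2 (-3.33 ± 0.21) and Ddx58 (-2.67 ± 0.25) fell.

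The count at 72 h in wild type was 2814, 1830 higher and 984 lower. It was 1809 in a fit of these 5 arrays alone, 1262 with a 2-fold minimum, 1597 without RA replicate 1 and 1563 without RA replicate 2. Quantile normalization shifted the genes of this comparison by a median of -0.11, and the share of calls that were higher went from 65.0% to 56.8%. All 13 RA-induced genes measured rose, also when adjusted over the list alone (camera adjusted p = 6.13e-18), among them Rarb (at least 3.43 ± 0.21) and the related RA hydroxylase Cyp26b1 (at least 3.35 ± 0.20). In retinoid metabolism and transport 7 of 13 rose and 1 fell, as when adjusted over the list alone (camera adjusted p = 0.000164), including Dhrs3 (3.68 ± 0.27) and the RA-binding protein Crabp2 (3.53 ± 0.25). Of 10 receptors and cofactors 3 rose and 0 fell, the same when adjusted over the list alone, and the list's median was -0.24 but its mean 0.47, with camera pointing up (adjusted p = 0.675). Of 19 Hox genes 15 rose and 0 fell, 16 when adjusted over the list alone (camera adjusted p = 1.56e-15), with Hoxa7 at least 2.78 ± 0.19, Hoxb1 at least 3.34 ± 0.29, Hoxb5 at least 3.00 ± 0.25 and Hoxb3 at 3.06 ± 0.25.

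Extraembryonic endoderm genes rose in wild type at 72 h, 14 of 17 with 0 falls, or 15 when adjusted over the list alone (camera adjusted p = 3.53e-06, and adjusted p = 0.114 with an estimated correlation). Pdgfra (2.93 ± 0.31), the endoderm factors Foxa2 (2.39 ± 0.26) and Gata6 (2.21 ± 0.37) and the collagen Col4a2 (2.25 ± 0.38) led them. Of 8 trophectoderm genes 5 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.000148), among them Krt18 (4.03 ± 0.36), Krt8 (2.77 ± 0.30), Krt7 (at least 2.08 ± 0.25) and Eomes, a T-box factor (2.04 ± 0.29). Of 28 pluripotency genes 3 rose and 10 fell, 3 and 12 when adjusted over the list alone (camera adjusted p = 0.000905, and adjusted p = 0.0600 with an estimated correlation). The nuclear receptor Nr0b1 (-2.17 ± 0.21), the growth factors Fgf4 (-1.80 ± 0.18) and Gdf3 (-1.14 ± 0.14) and Utf1 (-1.50 ± 0.18) fell. Of the core factors, chosen after their values were seen, Sox2 fell (-0.55 ± 0.14), while Pou5f1 had a difference of -0.33 ± 0.17 (adjusted p = 0.177) and Nanog of 0.36 ± 0.22 (adjusted p = 0.265). Cell cycle inhibitors rose, 7 of 13 with 0 falls and 8 when adjusted over the list alone (camera adjusted p = 0.00701), led by Cdkn1a (1.67 ± 0.20). Of 24 proliferation genes 0 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.000683), including cyclin D1, Ccnd1 (-1.42 ± 0.23), and the oncogene Mycn (-1.68 ± 0.30).

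Of the following 7 lists at 72 h in wild type only the first was called. Of 10 germ cell and meiosis genes 3 rose and 0 fell, 6 and 1 when adjusted over the list alone, with Rec8 at 2.20 ± 0.23 (camera adjusted p = 0.00972, and adjusted p = 0.111 with an estimated correlation). Of 18 genes of the LIF-STAT3 response 3 rose and 3 fell, also when adjusted over the list alone, with a median of 0.23 and camera pointing down (adjusted p = 0.850), and with Pramel7, a LIF-induced gene of the inner cell mass, rising (2.58 ± 0.32) and Myc, a target of STAT3, falling (-1.25 ± 0.24). Of 14 neural genes 3 rose and 3 fell, 4 and 3 when adjusted over the list alone (camera adjusted p = 0.982), Irx3 (2.56 ± 0.32) and N-cadherin, Cdh2 (1.85 ± 0.31), against Neurod1 (-1.93 ± 0.35). Primitive streak and mesoderm genes numbered 10, with 4 rises and 1 fall, the same when adjusted over the list alone (camera adjusted p = 0.335), and the fall was Bmp4, a growth factor (-2.15 ± 0.21). The Wnt response list of 6 had 2 rises and 1 fall, also when adjusted over the list alone (camera adjusted p = 0.711), with the antagonist Dkk1 up (2.30 ± 0.45). Of 5 fibroblast feeder markers 3 rose and 1 fell, 4 and 1 when adjusted over the list alone (camera adjusted p = 0.159), with Acta2 up (3.79 ± 0.46) and the surface antigen Thy1 down (-2.51 ± 0.39). Of 12 immediate early and stress genes 3 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.678), with Jun up (2.27 ± 0.40) and Egr1 down (-2.08 ± 0.37), both early response factors.

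Knockout cells after 72 h of RA, against their 8 h controls, had large rises in RA-induced and endoderm genes. Stra8 rose by 6.42 ± 0.30 (adjusted p = 3.57e-09, 2 arrays against 3), Cyp26a1 by 5.87 ± 0.32 and Hoxb2 by at least 5.28 ± 0.46. Gata6 rose by 4.84 ± 0.37 (adjusted p = 4.13e-07), Greb1l, a relative of the estrogen-regulated Greb1, by 4.58 ± 0.26 and Dab2, an endocytic adaptor of the yolk sac endoderm, by 4.23 ± 0.67. Cidea rose by at least 4.56 ± 0.20, and Srgn, the proteoglycan serglycin, by 4.42 ± 0.95. Ntn1, the guidance cue netrin, fell (-3.70 ± 0.17, adjusted p = 3.33e-09), as did Enox1 (-3.70 ± 0.34), the metallothionein Mt1 on chromosome 8 (-3.61 ± 0.20), Ddx58 (-3.25 ± 0.25) and Aire (-3.22 ± 0.60). The kinase Cdk6 fell (-2.81 ± 0.38), and Slc27a2 was lower by at least 2.79 ± 0.47.

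The knockout's count at 72 h was 2622, 1681 higher and 941 lower. It was 1188 with a 2-fold minimum, 1503 without RA replicate 1 and 1367 without RA replicate 2. Quantile normalization took the share of higher calls from 64.1% to 57.0%. All 13 RA-induced genes rose, also when adjusted over the list alone (camera adjusted p = 1.88e-17), with Nrip1 at 2.53 ± 0.19 and Cyp26b1 at 2.60 ± 0.20. Of 13 genes of retinoid metabolism and transport 8 rose and 0 fell, and 8 rose and 1 fell when adjusted over the list alone (camera adjusted p = 3.70e-05). Of 19 Hox genes 14 rose and 0 fell, 16 when adjusted over the list alone (camera adjusted p = 3.88e-16), with Hoxb4 at 3.70 ± 0.26 and Hoxa4 at least 3.56 ± 0.26. The endoderm list had 12 rises and 0 falls of 17, or 14 rises when adjusted over the list alone (camera adjusted p = 6.80e-09, and adjusted p = 0.0939 with an estimated correlation). Pdgfra (at least 4.14 ± 0.31), the transcription factor Gata4 (3.04 ± 0.38) and the collagen Col4a1 (2.59 ± 0.33) rose beside Gata6. Of 24 proliferation genes 0 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.00722, adjusted p = 0.0939 with an estimated correlation, and 0.133 with quantile normalization), led by Ccnd1 (-2.13 ± 0.23). Of 10 germ cell and meiosis genes 5 rose and 0 fell, 6 when adjusted over the list alone (camera adjusted p = 0.00722, and adjusted p = 0.108 with an estimated correlation). Pluripotency genes had 3 rises and 9 falls of 28, 4 and 9 when adjusted over the list alone, at a median of 0.04 with camera pointing down (adjusted p = 0.104, and 0.0216 with the LIF labels exchanged), and with Lefty1 up (2.76 ± 0.21) and the RNA-binding gene Lin28a down (-1.66 ± 0.21). Of 13 cell cycle inhibitors 4 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.0974, and 0.0407 with the block). Of 8 trophectoderm genes Krt8 (1.31 ± 0.30) and Krt18 (1.41 ± 0.36) rose, 0 fell, and 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.649).

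The difference of the 72 h responses was tested as an interaction, with 2 arrays against 3 in each genotype. Tagln had the largest, at -5.46 ± 0.34 for knockout minus wild type (adjusted p = 9.38e-07), and the contractile genes Acta2 (-3.81 ± 0.65), Acta1 (-3.26 ± 0.44) and Myl9 (-3.01 ± 0.46) followed. The value of Acta1 was computed from floored signals: every knockout array lay at the floor, in controls and at 72 h, as did 2 of the 3 wild-type controls. Cyp1b1, a cytochrome P450 of the mesenchyme (-3.21 ± 0.62), and Prss23, a serine protease (-2.84 ± 0.49), lay at the floor in both controls and in the knockout at 72 h, so that their values were computed from floored signals as well. Tagln lay at the floor in the controls of both genotypes, and its value was computed from floored signals too. The semaphorin and growth factor receptor Nrp1 on chromosome 8 (-2.87 ± 0.48), Krt18 (-2.62 ± 0.51, adjusted p = 0.0421), the endothelin Edn1 (-2.57 ± 0.48) and the Wnt carrier Wls (-2.51 ± 0.45) also responded less in the knockout. Ntn1 and Mt1, with negative interactions too, fell further in the knockout than in wild type. The 3 genes with a positive interaction were Gata6 (2.63 ± 0.53, adjusted p = 0.0473, or 2.27 and not called with the LIF labels exchanged), Lefty1 (1.56 ± 0.30, adjusted p = 0.0341) and Olig3 (1.55 ± 0.29, adjusted p = 0.0299). For Gata6 and Lefty1 the knockout started lower in controls, by -2.13 and -1.34, and stood 0.50 and 0.22 above wild type at 72 h, differences that were not called (adjusted p = 0.638 and 0.739).

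**Figure D3:**
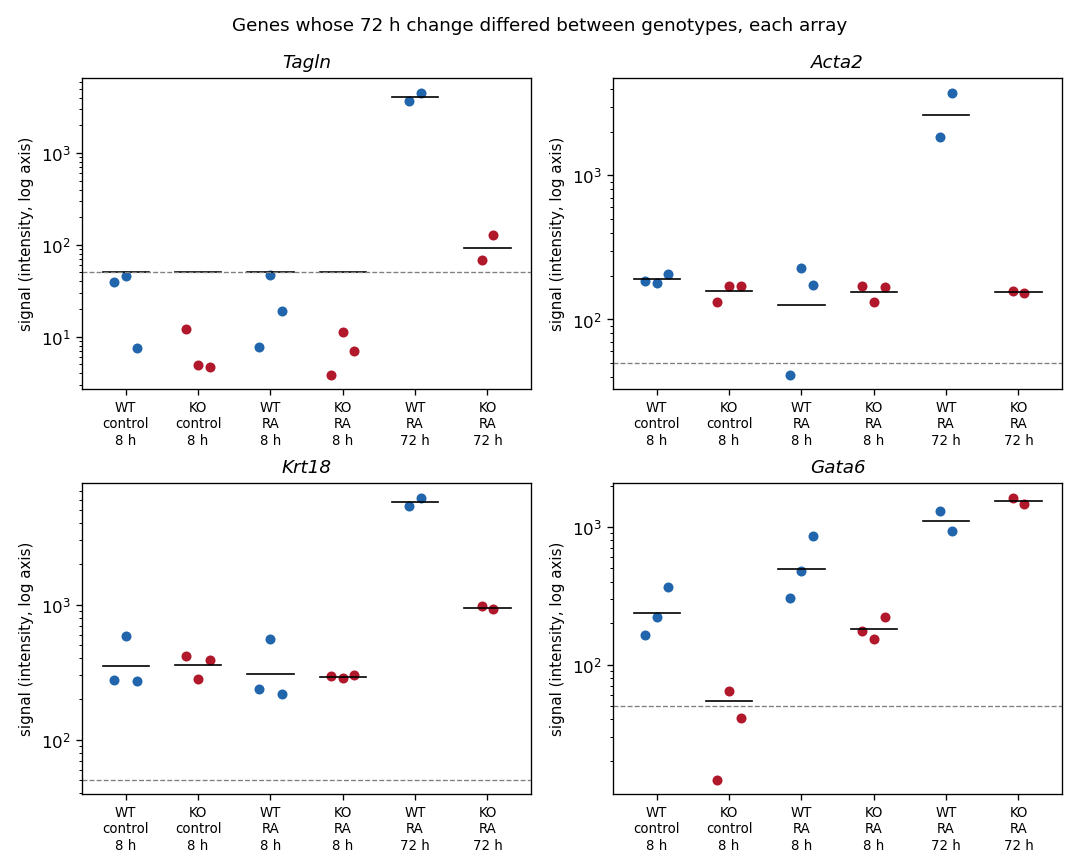
Signal of Tagln, Acta2, Krt18 and Gata6 (units, log axis) on each array of the 6 replicated groups, wild type in blue and knockout in red, with black lines at the mean of the floored log2 values and a dashed line at the floor of 50. At 72 h of RA, Tagln averaged 4103 units in wild type and 97.5 in the knockout.

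The 72 h interaction called 39 genes, 3 with positive and 36 with negative values for knockout minus wild type, and 35 of the 39 were also called between genotypes at 72 h. Of the 36, 33 changed less in the knockout than in wild type and 3 changed more. For some of the 33, such as Cd44 and Cnn1, the knockout's change is a floor value, as its arrays lay at the floor throughout this comparison. The count of 39 moved with the processing and with single arrays. It was 19 with quantile normalization, 188 with a floor of 100, 7 with log2 of the signal plus 32, 123 without the filter, 11 with the filter at 200, 83 without the intensity trend and 9 in a fit of these groups alone. Without wild-type arrays it was 15 (control replicate 1), 16 (control replicate 3) and 25 (RA replicate 2). Without knockout arrays it was 16, 11 and 13 for control replicates 1 to 3, 14 for RA replicate 1 and 1 for RA replicate 2, where only Tagln was called (-5.92). Of 8 trophectoderm genes 0 had positive and 3 negative interactions, 5 when adjusted over the list alone (camera adjusted p = 6.12e-12): Krt18, Eomes (-2.04 ± 0.41) and Krt7 (-1.75 ± 0.35, adjusted p = 0.0448, or 0.0573 with the block). None of the 13 RA-induced genes was called, nor any when adjusted over the list alone, with a median of -0.30 (camera adjusted p = 0.00121). Of 28 pluripotency genes only Lefty1 was called, also when adjusted over the list alone (camera adjusted p = 0.00295, and adjusted p = 0.157 with an estimated correlation). Of 17 extraembryonic endoderm genes only Gata6 was called, also when adjusted over the list alone, at a median of 0.62 (camera adjusted p = 0.00649, adjusted p = 0.496 with an estimated correlation, and 0.0809 over 16 genes tested with the LIF labels exchanged). Of 10 streak and mesoderm genes 0 had positive and 1 a negative interaction, Eomes, or 3 when adjusted over the list alone (camera adjusted p = 0.0363, adjusted p = 0.243 with an estimated correlation, 0.0739 with the block, 0.0611 with quantile normalization and 0.0874 with the LIF labels exchanged). Cyp26a1's own interaction at 72 h was 0.25 ± 0.46 and not called. Of the 15 genes named and called in this interaction, only Tagln kept its call without any single array.

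Withdrawal of LIF for 8 h was tested on 1 array per genotype against the 3 control arrays of each, over 10476 genes, and limma called 0 genes without a block. The arrays labelled without LIF both belong to replicate 1, and with the replicate number as a block 227 genes were called, 153 higher and 74 lower, with 3 residual degrees of freedom. With the labels exchanged, and no block, 192 were called, 60 higher and 132 lower. At an unadjusted p under 0.05 there were 285 genes without the block, with a smallest adjusted p of 0.314, and 1224 with it. The 285 are under the share of 0.05 of the genes tested that would pass with no effect at all. The largest evidence without the block was for Bcl2l11, the proapoptotic gene also called Bim, with a difference of -1.01 ± 0.14 (adjusted p = 0.314), or -0.98 ± 0.16 with the block (adjusted p = 0.00723). Socs3, the feedback inhibitor that LIF induces through STAT3, had a difference of 1.13 ± 1.25 (adjusted p = 0.999), and 3.89 ± 0.24 with the block (adjusted p = 4.51e-06), so that it read higher where the label says LIF was absent. Bcl3 (1.11 ± 0.77) and the adhesion molecule Icam1 (0.73 ± 0.39), both STAT3-responsive, were likewise not called, and stood at 2.79 ± 0.17 and 1.54 ± 0.14 with the block, both called. Of 17 LIF-STAT3 genes measured in this fit 0 rose and 0 fell, at a median of 0.28 (camera adjusted p = 0.124, and 1.59e-14 with the block, pointing up). On the replicate 1 control array labelled with LIF, 10 of these 17 genes read below the other 7 arrays of their genotype labelled so, in wild type and in the knockout alike. On the array labelled without LIF 0 did in wild type and 1 in the knockout. The 15 extraembryonic endoderm genes had a median of -0.38 with 0 called (camera adjusted p = 0.000844 pointing down, adjusted p = 0.669 with an estimated correlation, and 0.573 pointing up with the block). With the block the 28 pluripotency genes (camera adjusted p = 0.000136) and the 12 immediate early and stress genes (camera adjusted p = 0.000554) ran higher too. Without the filter 1 gene was called, Bcl2l14, a BCL2 relative chosen after its values were seen (0.70, adjusted p = 8.61e-06).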

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

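The tests for fibroblast cells, for contractile and RA-induced genes as groups, and of arrays left out for a single deviant array were chosen only after the result was seen, and the test of overlap and that for a weaker response overall were set before. The 72 h response to RA differed between genotypes for 39 genes, by a test of the difference itself, and the values below are those differences on the log2 scale. Values for knockout minus wild type were negative for the actin-binding gene Tagln (-5.46), the actins Acta2 (-3.81) and Acta1 (-3.26), the myosin light chain Myl9 (-3.01) and the cytochrome P450 gene Cyp1b1 (-3.21). They were negative as well for the receptor Nrp1 (-2.87), the protease Prss23 (-2.84), the keratin Krt18 (-2.62), the endothelin Edn1 (-2.57) and the Wnt carrier Wls (-2.51). They were positive for the endoderm factor Gata6 (2.63), the Nodal antagonist Lefty1 (1.56) and the neural tube gene Olig3 (1.55). No group held 4 or more arrays, so single arrays far from their group were not searched for.

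Of the 36 genes with negative values, 33 changed less in the knockout than in wild type and 3 changed more. Over the 36, the median change from control was 2.43 in wild type and 0.05 in the knockout, with 33 and 8 of them called higher. In some of the 36, such as Cd44, Cnn1 and Gbp2, the knockout lay at the floor in controls and at 72 h. A change under the floor reads as 0, so the knockout's median and its smaller changes are in part floor values. The 72 h arrays of the genotypes did not overlap for 36 of the 36 genes, which decides nothing about a single deviant array, since the genes were picked for this difference (chance gives 1 in 3 for a gene not so picked). The calls rest on single arrays: without replicate 2 of the knockout at 72 h, 1 gene was called. A single array as the whole cause is argued against by genes picked without it, the 36 that each fit put lowest by p. Over these the array left out still lay apart from the other genotype's 72 h mean, which took part in the picking, by a median between -1.75 and -1.99 for each of the 4 arrays. A weaker response overall is argued against as the whole cause: over 4553 genes called in the mean 72 h response, in which RA and time in culture are mixed, the knockout's median shortfall was 0.0198, against a median absolute response of 0.668. All 13 RA-induced genes rose in both genotypes, by medians of 3.53 in wild type and 2.99 in the knockout. A weaker response of the RA-induced genes stays open as a part of the cause, as their median difference was -0.30 (camera adjusted p = 0.00121, or 0.0488 with an estimated correlation). Fibroblast feeder cells in the wild-type 72 h cultures stay open: abundant fibroblast genes responded less in the knockout by a median of -1.12, computed from floored values, but -0.05 with wild-type replicate 1 alone at 72 h and -2.20 with replicate 2 alone. On these 2 arrays Col1a1 read 76.8 and 302 units, Col1a2 91.3 and 432, Col3a1 56.6 and 253 and Dcn 24.2 and 210, while Tagln read 3654 and 4552. The difference computed from floored values thus rests on replicate 2, and Tagln was high on both. Before flooring, replicate 1 also read above the knockout's 72 h means of 11.8 (Col1a1), 58.5 (Col1a2), 25.0 (Col3a1) and 10.4 units (Dcn). Lum and Postn went the other way, at 2.46 and 2.46 units on replicate 1 against means of 22.8 and 5.92. The floored median of replicate 1 therefore does not show that fibroblast signal was absent there. A loss in the knockout of a contractile, mesenchyme-like program is the biological candidate. The other 19 contractile and adhesion genes measured, at a median of -0.85, responded less as a group (camera p = 0.000116 with an estimated correlation), which may equally come from cells of another type. The 2 of them called, Cnn1 (-2.05, computed from floored values) and Tpm1 (-2.26), are among the 36 genes, so that this test in part restates the pattern. The collagens and Dcn were not tested gene by gene, as fewer than 2 arrays reached 100 units, and a difference in culture density was not tested.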

How the results depend on the processing

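The removal of the genes of chromosomes 8 and 19, the list tests with the block, the block for LIF withdrawal and the exchange of LIF labels were chosen only after the data were seen, and the other alternatives were planned. Adding the replicate number as a block took the calls from 103 to 275 for RA at 8 h in wild type and from 109 to 342 in the knockout. Between genotypes it took them from 528 to 1069 in controls, from 525 to 1114 after 8 h of RA and from 463 to 1004 after 72 h, with every earlier call kept. For LIF withdrawal it took them from 0 to 227, as both arrays labelled without LIF share a number, and the other counts stayed within 1.5 times. Exchanging the labels with and without LIF of the replicate 1 controls gave 160 genes for RA at 8 h in wild type and 192 for LIF withdrawal; the cause of the former was not tested. Testing every gene without the filter gave 67 and 57 genes for RA at 8 h in wild type and knockout, 2 for the 8 h interaction, 123 for the 72 h interaction and 1 for LIF withdrawal; the cause was not tested. A fit of only the groups compared, which has fewer arrays to estimate the spread, gave 5, 24, 14, 34, 73, 1809 and 9 genes for RA at 8 h in wild type and knockout, the genotypes in controls, at 8 h and at 72 h, wild type at 72 h, and the 72 h interaction. The added 2-fold minimum, which only removes genes, left 60 for RA at 8 h in wild type, 135, 126, 267 and 143 between genotypes in controls, at 8 h, at 72 h and over their mean, and 1262 and 1188 at 72 h in wild type and knockout. Without chromosomes 8 and 19, whose genes hold many of the calls, 201, 148, 274 and 1327 were left between genotypes in the same order. The 72 h interaction moved from 39 to 19 with quantile normalization, 188 with a floor of 100, 7 with the signal plus 32, 11 with the filter at 200 and 83 without the intensity trend. Its count was thus higher with a higher floor or no filter, and lower with no floor or a stricter filter. Arrays at the floor show no spread, which can make standard errors too small. How far this bears on the 39 calls was not tested. The correlation of the 8 h responses was 0.697 with the filter at 200, where fewer dim genes were tested. Of the list tests 42 were called, against 16 with an estimated correlation and 68 by fry with the block, which asks another question.

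Leaving out each array in turn, which lowers the number of arrays, gave 58 to 135 genes for RA at 8 h in wild type, 36 to 75 in the knockout, and 0 for the 8 h interaction and for LIF withdrawal (limma, 211 and 285 genes at an unadjusted p under 0.05 with every array). Between genotypes it gave 253 to 425 in controls, 243 to 360 at 8 h, 177 to 245 at 72 h and 1510 to 2044 over their mean. At 72 h it gave 1563 to 2619 in wild type, 1367 to 2138 in the knockout and 1 to 41 for the interaction. The correlation of the 8 h responses lay between 0.505 and 0.602. Of 498 pairs of a comparison and a gene that the naming rule selects, 377 were called, and 0 of these reversed direction under any setting. Calls were lost for 25 pairs with quantile normalization, 45 with a floor of 100, 28 with the signal plus 32, 77 without the filter, 9 with the filter at 200, 23 without the trend, 135 of 431 with only the groups compared 1 with the block and 16 with the LIF labels exchanged, while 19 gained a call with the block. Without any single array 15 of 27 calls of such genes held for RA at 8 h in wild type, 13 of 29 in the knockout, 14 of 34, 15 of 33 and 18 of 38 between genotypes in controls, at 8 h and at 72 h, 57 of 63 over their mean, 61 of 71 and 51 of 67 at 72 h in wild type and knockout, and 1 of 15 for the 72 h interaction. Signal over background limits what was seen of dim genes: changes that stayed under 50 units read as 0, and folds from that floor are lower bounds.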

Other observations

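The group tests of hypoxia, imprinted and germ line genes, the X chromosome test, the array scaling test, the tests along chromosome 19 and of parts of chromosome 8, the tests of the LIF labels, and the draw of splits that part every replicate pair were chosen only after the result was seen, and the other tests of this part were set before. Genes of hypoxia and glycolysis, tested as 1 list, ran higher in the knockout. Of the 29 measured, 17 rose and 2 fell in the mean of the conditions, at a median of 0.37. Bnip3 (1.95), Ndufa4l2 (1.51), the lactate exporter Slc16a3 (1.26) and the triose phosphate isomerase Tpi1 (1.11) rose most. The lactate dehydrogenase Ldha (0.40), the phosphoglycerate mutase Pgam1 (0.54) and the pyruvate dehydrogenase kinase Pdk1 (0.52) rose by less. The falls were Ddit4, a stress inhibitor of mTOR (-0.76), and P4ha2, a collagen hydroxylase (-0.96), both hypoxia targets, and Gapdh (0.12), Hk1 (-0.12) and Hk2 (0.09) were not called. Without Bnip3, Ndufa4l2, Slc16a3, Tpi1 and Ndrg1 the list was still higher (camera p = 0.00178 with an estimated correlation, 24 genes). Of the 29 genes, and of these 24, 4 lie on chromosomes 8 or 19, whose genes shifted as groups, and the list was not tested without those 4. A shift of this mixed list may underlie Bnip3, and the fall of Ddit4 and P4ha2 and a difference in culture density, which was not tested, keep this open.

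Imprinted genes ran lower in the knockout. Of 25 measured, 0 rose and 11 fell in the mean of conditions, at a median of -0.56, with the growth inhibitor Cdkn1c and Dlk1, a Notch ligand relative, as the genes that prompted the test. The other 23 had camera p = 0.0226 with an estimated correlation. Within conditions this camera p was 0.0575 in controls, 0.0748 after 8 h of RA and 0.0302 after 72 h. A change in imprinting between the lines stays possible, though neither methylation nor alleles were analysed here.

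Fmr1nb (-3.72), Mageb16 (-3.22) and Rhox5 (-2.67), on the X chromosome, were among the largest falls, and the germ line gene Dazl (-1.51), elsewhere, fell by less. Loss of the whole X chromosome's dosage is argued against, since the median over 369 X-linked genes was -0.0797. Germ line genes that DNA methylation represses remain open as a group: with Fmr1nb, Mageb16 and Rhox5 left out, 0 of 18 rose and 8 fell, and camera gave p = 0.135 with an estimated correlation. The fall may thus be a matter of a few loci, and no test here separates the knockout from the history of the cell line.

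The LIF-STAT3 genes ran against the labels in replicate 1, with a median of -0.99 over 17 genes for labelled with minus labelled without LIF. Socs3 read 367 and 215 units on the wild-type and knockout controls labelled with LIF, and 3800 and 4551 units on the arrays labelled without it, inside the range of the other arrays of each genotype (2628 to 4484 and 3525 to 6001 units). Array scaling is argued against, as the median over all 10476 genes was 0.00370. An exchange of the 2 control arrays in both genotypes is consistent with these values, whether of labels, of samples or of media, which no test here separates. If it took place, the differences for LIF withdrawal have the wrong sign and 1 of the 3 controls of each genotype lacked LIF. The counts of the other comparisons then stood at 160 for RA at 8 h in wild type and within 1.5 times of the given ones elsewhere.

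The shift of chromosomes 19 and 8 was weighed as a difference in copy number between the lines. Array scaling is argued against, since the median of the other autosomes departed from 0 by at most 0.0468. The choice of probe set is argued against too, as chromosome 19 probe sets not chosen for their gene had a median of 0.457. An extra copy of chromosome 19 in some or all knockout cells would raise every part of it, and the lowest window stood at 0.399; genes brighter than 500 units had a median of 0.53, beside 0.585 for 3 copies against 2. For a change of the whole of chromosome 8, the rule set before asked for more windows at or above 0 than the 4 of 21 found, so it decided nothing. Read after the result was seen, windows as high as 0.0511 argue against an even change along it. In the windows near 0, the 184 probe sets not chosen for their gene had a median of 0.00597. A difference in copy number of parts of it stays open: probe sets not chosen for their gene lay lower in the low windows than in the others by -0.420. These measure the same genes on the same arrays, so they bear on the choice of probe set and not on the cause. Nor do the values tell a loss in the knockout from a gain in wild type. No biological explanation by the knockout itself was tested, and DNA was not analysed here.

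Other splits of the arrays were counted for each comparison of at least 3 arrays per group. The 10 splits of 6 arrays are too few for a share under 0.05: 1 of the 10 gave as many genes as the real split in each of 4 comparisons. RA at 8 h gave 103 genes in wild type against at most 2 in another split, and 109 in the knockout against at most 0. The genotypes gave 528 in controls against at most 20, and 525 after 8 h of RA against at most 1. Only 4 of the 10 splits put the arrays of each replicate number apart as the real split does, and the other 3 of these gave 0 genes. Over the mean of conditions the genotypes gave 2016 genes, which 1 of 100 splits reached, the real split, and the highest other gave 1044. This share treats the arrays as exchangeable, and whether repeats were separate cultures is not known. It therefore bears on these arrays only and does not exclude chance between cultures. Of these 100 splits 11 part every replicate pair, so 100 of the 128 such splits were drawn as well: 1 reached the real count, the real split, and the highest other gave 611, with 1 of the 8 pairs swapped. For the 8 h interaction 100 of 100 splits gave as many as its 0 genes, which a count of 0 makes certain, so that this comparison decides nothing. The highest gave 1473, which points to a structure of the samples. That one was among the 17 splits that part every replicate pair, and splits that part fewer pairs gave at most 276; such splits can set wild-type against knockout arrays, so that the genotype difference enters them.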
